A study of Homo sapiens with 12 samples.

How the data were processed

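Total RNA from 12 samples was hybridised to Affymetrix HuGene arrays, 500 ng per sample per the labels' protocols. The samples are HCT116 and DLD1 cells in which, per the labels, 1 allele of the mutated PI3K catalytic subunit had been removed, so that either the mutant or the wild-type allele remained; the mutation differs between the lines. Cells were held in 0.5% serum for 19 h before harvest per the labels' protocols. Each of the 4 groups has 3 arrays, which the labels call biological replicates, and the labels number them 1 to 3 in every group.

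The authors deposited log2 expression values for 28869 transcript clusters; background correction, summarisation and normalization are not given in the sources used here. Array medians differed by about 0.1, so the columns had not been left quantile-identical. The authors also deposited a table of selected clusters per line with a p-value, a fold ratio and the log2 group values per the file headers. Per the file headers those p-values came from a moderated test with no correction for multiple testing, after an ANOVA filter at 0.05 and with a fold cut-off of 2, and the array annotation was on the hg19 build. The group columns of those deposited tables carry numbers that no sample label holds, and they were assigned to groups because their log2 values equal the group means here to within 1.3e-06. No detection p-values were used here, so signal over background was not assessed, and the number of arrays limits the precision of every value. No per-sample columns other than these 12 were present.

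Gene symbols came from the platform annotation, looked up by gene identifier in NCBI's gene table for GRCh38.p14, which was used for names and for the order of neighbouring genes only; no coordinates are given because the builds differ. Of the transcript clusters 19310 had 1 symbol, 1752 had several and 7807 had none here. Clusters with several symbols or none were left out of the gene-level fits. For the 685 genes with more than 1 cluster the cluster with the highest mean over all arrays was kept, which left 18377 genes. Where other clusters of a named gene existed they had the same sign as the one used, except for MUC12 and HLA-DPB1 in DLD1. The transcript of the targeted gene is not reported here.

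Group means were fitted to the log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with all 12 arrays in 1 model, 8 residual and 5.17 prior degrees of freedom. The contrasts were mutant-only minus wild-type-only in each line, their mean and their difference. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all genes, and a gene was counted at an adjusted p under 0.05. The 24 gene lists, with 613 distinct genes of which 551 were measured, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 24 lists; fry's directional p tests whether a list's genes move, on balance, one way and does not compare them with other genes. Of 8 lists called in HCT116 by camera 1 held with the estimated correlation, and of 10 called in DLD1 none did. Regrouped arrays with 0 called genes still had up to 7 lists called at the preset correlation. Such calls are therefore weak by themselves, however small the p. Calls "adjusted over the list alone" were adjusted over the members of that list. Overlaps were compared with the product of the list sizes over all genes and tested with Fisher's exact test.

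Design, tests, lists, the alternatives named as planned and the rule for naming genes were fixed, as choices made before the data were examined. The rule took, per line, the 8 largest rises and the 8 largest falls among called genes with an official symbol whose arrays did not overlap between genotypes; up to 3 called members per list; the 6 highest and 6 lowest genes called in both lines; the 4 leading genes with opposite calls, both ranked by the smaller of the changes; the 5 highest and 5 lowest differences between lines; and the 3 highest and 3 lowest folds of each deposited table. Other list members named as examples were chosen after their values were seen.

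The labels number the arrays but state no pairing, which was judged from the deviations. Deviations from the group means correlated by 0.129 to 0.462 in all 6 pairs of same-numbered arrays of one line, above the minimum of 0.1 set in advance, and by -0.321 to 0.17 in pairs of different numbers. In DLD1 the pairing was less clear: wild-type-only replicate 2 correlated by 0.17 with mutant-only replicate 1 and by 0.129 with mutant-only replicate 2. Same-numbered arrays of different lines correlated by 0.0657 to 0.471. The fit with the replicate number within each line as a block (4 residual degrees of freedom) was therefore given beside results whose call it changed or whose count it moved by more than 1.5 times.

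Alternatives were the mean of all clusters of a gene, a filter at the 40th percentile of mean signal, quantile normalization, median centring, eBayes with trend and robust settings, the arrays of 1 line alone, array weights, a replicate block, other thresholds, every cluster, and each array left out in turn. Cyclic loess, a block shared by both lines, the arrays numbered 3 left out together and lists without low-signal members were added after seeing the data. The fit was tested on simulated data for the same 18377 genes, with 200 changed genes, 50 at each fold: for the HCT116 comparison it recovered 28 at 1.25-fold, 49 at 1.5-fold, 50 at 2-fold and 50 at 3-fold with 8 false calls, and for the DLD1 comparison 27, 48, 50 and 50 with 5 false calls. For the difference between lines it recovered 7, 34, 49 and 50 with 8 false calls. The simulated noise was drawn independently for each gene and array. The false calls therefore do not give the error rate for these arrays, whose deviations correlate.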

Results

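Gene expression was measured on Affymetrix human gene arrays in HCT116 and DLD1, a pair of colorectal cancer cell lines that each carry an activating mutation in one allele of a PI3K catalytic subunit, the lipid kinase that relays growth factor signals to AKT. Gene targeting had left either only the mutant allele (mutant-only) or only the wild-type allele (wild-type-only) in cells derived from each line. The 12 arrays form 4 groups of 3 labelled biological replicates, from cells kept for 19 h in 0.5% serum. The array medians lay between 7.42 and 7.53 on the log2 scale. Pearson correlations across transcript clusters were 0.9952 to 0.9983 within a group, 0.9925 to 0.9966 between genotypes of one line and 0.9519 to 0.9633 between lines, and transcript clusters are not independent replicates. Every change is given as mutant-only over wild-type-only, with the SD of 3 arrays for levels and the SE of the fit for changes. The number of arrays limits the precision, and each genotype of a line is represented by 1 derived line, so that differences between derived cells and differences of genotype enter the same comparison.

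The first comparison asked which transcripts differed between mutant-only and wild-type-only HCT116 cells. EHF (transcript cluster 7939314), an epithelial ETS transcription factor, rose from a log2 level of 7.72 ± 0.17 to 10.00 ± 0.22 (SD, n = 3), a 4.85-fold increase (log2 change 2.28, SE 0.112, adjusted p = 5.41e-08). DPP4 (8056222), a cell-surface dipeptidyl peptidase, rose 4.27-fold and the neurotrophin BDNF (7947230) rose 4.13-fold, from 7.22 ± 0.07 to 9.27 ± 0.10 (SD, n = 3). The opposite change was largest for GPR15 (8081214), a chemoattractant receptor, which fell from 9.34 ± 0.20 to 6.96 ± 0.23 (SD, n = 3) and was 5.23-fold lower (SE 0.131 on the log2 scale, adjusted p = 1.01e-07). The neuroendocrine secretory protein SCG2 was 4.81-fold lower, the serine palmitoyltransferase subunit SPTSSB 4.51-fold lower and the immediate early nuclear receptor NR4A2 4.26-fold lower. TENM3, a teneurin adhesion receptor, rose 3.33-fold, ZNF711 3.09-fold, the peroxidase PXDN 2.88-fold, DENND5B 2.72-fold and NETO2, an auxiliary subunit of glutamate receptors, 2.70-fold. GALNT5, which starts mucin-type O-glycosylation, was 3.89-fold lower, NAV3 3.65-fold, RGCC 3.61-fold and PLAT, the tissue plasminogen activator, 3.21-fold (adjusted p = 1.72e-05). For each of these 16 genes the 3 arrays of one genotype lay on one side of the 3 of the other, as the rule for naming them required. The largest adjusted p among the 16 was that of PLAT.

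In all, 1132 of 18377 genes changed in HCT116, 738 higher and 394 lower, by a median of 1.255-fold. At least 2-fold changes were found for 38 genes, 23 higher and 15 lower. The arrays of both genotypes did not overlap for 4046 genes, or 22.0% against the 10% that chance gives for 3 against 3 arrays, a design whose smallest exact two-sided p is 0.1. With the replicate number as a block, given because same-numbered arrays deviated together, the count was 1808 (1185 higher, 623 lower). In both fits 1122 genes passed. It was 694 without HCT116 wild-type-only replicate 1, 681 without HCT116 mutant-only replicate 1 and 665 with the HCT116 arrays alone in the fit.

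The p53 target genes rose together in HCT116. Of 22 measured members 10 rose, 1 fell and 11 did not pass (15 and 1 adjusted over the list alone), with a median log2 change of 0.22 and a camera adjusted p of 1.66e-10 (adjusted p = 0.00398 with an estimated correlation). TP53INP1, a stress protein that binds p53, rose by 0.70 (SE 0.0686, adjusted p = 3.49e-05), the cell cycle inhibitor CDKN1A from 9.34 ± 0.07 to 9.98 ± 0.17 (SD, n = 3, adjusted p = 0.000631) and SESN1 by 0.63. MDM2, the ubiquitin ligase that degrades p53, rose by 0.40, the death receptor TNFRSF10B by 0.40 and the repair factor DDB2 by 0.53. The apoptosis effector BAX was the 1 member that fell, by 0.24, and its call was lost without HCT116 wild-type-only replicate 1 (0.0814) or 2 (0.0636) or mutant-only replicate 1 (0.0979) or 2 (0.0638). No other list of the 24 kept its call in HCT116 with an estimated correlation.

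Sterol and fatty acid synthesis genes were higher in HCT116 mutant-only cells: 7 of 24 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 5.15e-06, adjusted p = 0.382 with an estimated correlation). The desaturase FADS2 rose by 0.44 and LSS, the lanosterol synthase, by 0.36 (SE 0.0633, adjusted p = 0.00354). Of 29 genes of the amino acid stress response, 4 rose and none fell (9 and 0 adjusted over the list alone, camera adjusted p = 7.24e-06, adjusted p = 0.382 with an estimated correlation). These were DDIT4, an inhibitor of mTOR complex 1, which rose 2.08-fold (adjusted p = 0.00508), STC2, SESN2 and the cystine transporter subunit SLC7A11. The SLC7A11 call was lost without any 1 of the 6 HCT116 arrays (adjusted p 0.0547 to 0.109), the STC2 call without wild-type-only replicate 1 (0.0534) or mutant-only replicate 3 (0.0515), and the SESN2 call without wild-type-only replicate 1 (0.0611), wild-type-only replicate 2 (0.0592) or mutant-only replicate 3 (0.0649).

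Among signalling lists in HCT116, of 26 PI3K, AKT and mTOR components 6 rose and none fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.0148, adjusted p = 0.56 with an estimated correlation). The leading members were PI3K regulatory subunits, PIK3R3 at 6.92 ± 0.14 and 8.24 ± 0.04 (SD, n = 3; 2.49-fold, adjusted p = 1.01e-07), and PIK3R1, which rose by 0.49 (adjusted p = 0.000735). That list's call ended without HCT116 wild-type-only replicate 1 (adjusted p = 0.0617), with dim genes left out (0.0609), after quantile normalization (0.0626) and after cyclic loess (0.069). ERK pathway output genes were lower: 4 of 26 fell and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.00451, adjusted p = 0.537 with an estimated correlation, fry adjusted p = 0.0809). The ERK phosphatase DUSP5 fell by 0.42, the pathway inhibitor SPRY4 by 0.42 and the growth factor EREG by 0.38. TGF-beta and YAP targets were higher, with 5 of 24 rising and none falling (6 and 0 adjusted over the list alone, camera adjusted p = 0.00572, adjusted p = 0.382 with an estimated correlation), among them F3, tissue factor, by 0.44 (adjusted p = 0.000573), and CCN1 by 0.32, a call lost with the HCT116 arrays alone in the fit (0.0637). Autophagy and lysosome genes were also higher: ATG12, ATG14 and the lysosomal regulator TFE3 rose, and none of 24 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.00572, adjusted p = 0.382 with an estimated correlation). Among 23 NF-kB targets and chemokines NFKBIA, the inhibitor of NF-kB, rose by 0.49 and none fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.036, adjusted p = 0.537 with an estimated correlation). The NF-kB list lost its call without HCT116 wild-type-only replicate 2 (0.0656), wild-type-only replicate 3 (0.0897) or mutant-only replicate 1 (0.181), with dim genes left out (0.0809) and by fry (0.0809).

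The remaining lists did not pass in HCT116. FOXO-activated genes gave 3 higher and 2 lower of 24 (5 and 5 adjusted over the list alone, camera adjusted p = 0.384), and receptor tyrosine kinases and adaptors 3 and 2 of 25 (6 and 4 alone, 0.833, mean 0.0149 and median -0.00636). Glycolysis and HIF targets gave 3 and 5 of 29 (4 and 6 alone, 0.614). Among these the glucose transporter SLC2A1 rose by 0.48 and the enolase ENO2 fell by 0.49. Mesenchymal genes gave 5 and 1 of 28 (6 and 1 alone, 0.0586), a list mean of 0.0838 and a median of -0.000567. Fibronectin FN1 rose 1.94-fold (7.35 ± 0.02 to 8.31 ± 0.09, SD, n = 3, adjusted p = 5.44e-07) and smooth muscle actin ACTA2 rose by 0.59. The mesenchymal list passed without HCT116 wild-type-only replicate 1 (0.0124) or mutant-only replicate 1 (0.0306), after quantile normalization (0.0318) and after cyclic loess (0.0247), and without its low-signal members (0.0276). It did not pass by camera with an estimated correlation (adjusted p = 0.66) or the replicate block (0.133), or by fry (0.0519). Epithelial junction and keratin genes gave 4 and 3 of 27 (5 and 4 alone, 0.664) and matrix remodelling genes 3 and 2 of 34 (4 and 3 alone, 0.721). Interferon-stimulated genes gave 0 and 3 of 35 (3 and 3 alone, 0.833), and heat shock and unfolded protein genes 1 and 1 of 19 (1 and 1 alone, 0.222). Intestinal differentiation genes gave 2 and 1 of 34 (2 and 1 alone, 0.833), with MUC12 rising by 0.88 and CA2 falling by 0.41, a call lost without the arrays numbered 3 (0.0539). WNT targets and intestinal stem cell genes gave 1 and 1 of 22 (1 and 1 alone, 0.833), with the ERBB regulator LRIG1 rising 2.37-fold. In these last 2 lists the mean was above 0 and camera's direction was down. HLA and antigen presentation genes gave 0 and 1 of 13 (0 and 2 alone, 0.149), HLA-DPB1 falling by 0.63. For 38 cell cycle and DNA replication genes MYBL2 rose and none fell (3 and 0 alone, 0.0586), and MYBL2 lost its call with the HCT116 arrays alone in the fit (0.0673) and without the arrays numbered 3 (0.061). The cell cycle list passed with the replicate number as a block (0.0248), without its low-signal members (0.045) and without HCT116 wild-type-only replicate 2 (0.000113), mutant-only replicate 1 (0.00161) or mutant-only replicate 2 (0.0418). It did not pass by camera with an estimated correlation (adjusted p = 0.819) or by fry (adjusted p = 0.497).

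The second comparison asked the same of DLD1. KRT20 (8015124), the keratin of differentiated intestinal epithelium, fell from 10.92 ± 0.06 to 6.78 ± 0.14 (SD, n = 3) and was 17.7-fold lower in mutant-only cells (SE 0.0707 on the log2 scale, adjusted p = 4.7e-13), the largest change in either line among genes with a symbol. VGLL1 (8170179), a cofactor of TEAD transcription factors, was 6.60-fold lower and the cytidine deaminase APOBEC3G 3.76-fold lower. HLTF (8091354), a helicase-like factor of DNA damage tolerance, rose from 6.52 ± 0.15 to 9.41 ± 0.18 (SD, n = 3), a 7.45-fold change (SE 0.0919 on the log2 scale, adjusted p = 5.29e-10). QPRT (7994609), an enzyme of NAD synthesis, rose 7.18-fold, from 8.47 ± 0.30 to 11.31 ± 0.17 (SD, n = 3), and SH3BGRL 5.50-fold. The RNA-binding protein CELF2 rose 3.48-fold, the chemokine CCL26 2.80-fold, SCEL 2.67-fold and the mucin MUC13 2.63-fold, and the manganese transporter SLC30A10 rose by 1.58 on the log2 scale. HOXD10 was 3.46-fold lower, the monoamine oxidase MAOB 3.37-fold, the YAP target ANKRD1 3.02-fold, the creatine synthesis enzyme GATM 2.75-fold and the lysosomal channel MCOLN3 2.73-fold. The same rule required that in these 16 genes the 3 arrays of one genotype did not overlap the 3 of the other. The largest adjusted p among the 16 was that of SCEL (1.31e-05).

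In all, 1612 of 18377 genes changed in DLD1, 1041 higher and 571 lower, by a median of 0.32 on the log2 scale. Changes of at least 2-fold numbered 54, 28 higher and 26 lower. Arrays of the genotypes did not overlap for 5200 genes, or 28.3% against 10% by chance. Of the calls 64.6% were higher, and after median centring of each array 80.1% of 2087 (1671 higher, 416 lower). The blocked fit called 2482 genes (1621 higher, 861 lower), of which 1605 passed in both fits. The count was 939 without DLD1 wild-type-only replicate 1, 1034 without DLD1 mutant-only replicate 1, 1062 without DLD1 mutant-only replicate 3, and 995 without the arrays numbered 3 of all groups. It was 4705 (2754 higher, 1951 lower) with array weights. The weights gave DLD1 wild-type-only replicate 1 a weight of 6.23 and the other arrays 0.436 to 1.72.

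**Figure D1:**
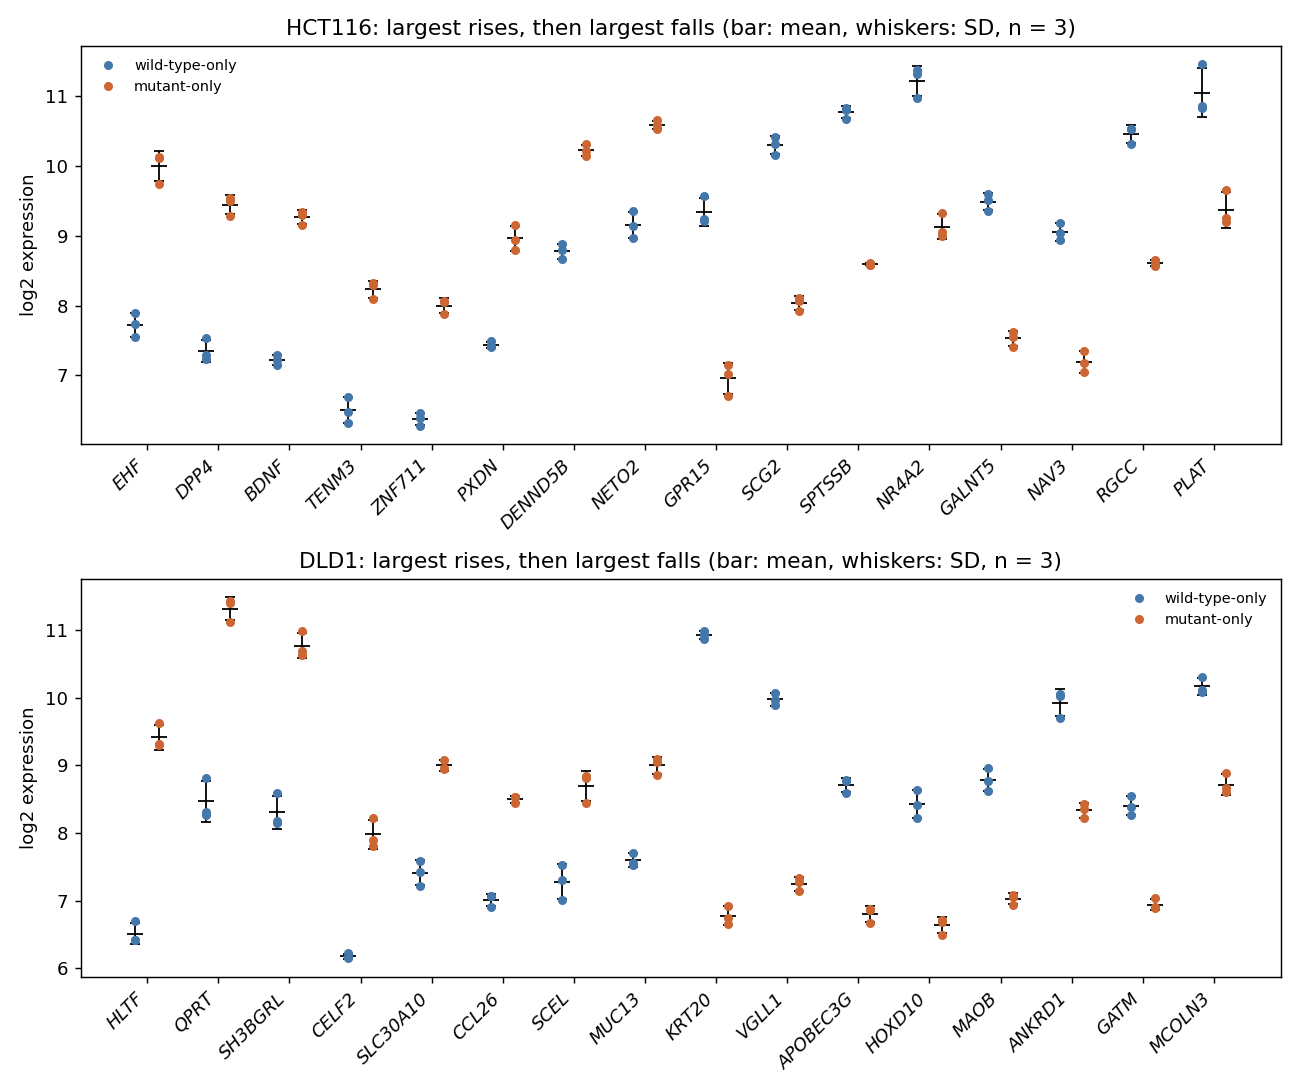
Log2 expression (y axis) of the 8 genes with the largest rises and the 8 with the largest falls (x axis) in HCT116 (upper panel) and DLD1 (lower panel), with 1 point per array, blue for wild-type-only and orange for mutant-only, the mean as a bar and the SD (n = 3) as whiskers. EHF lies at 7.72 and 10.00 in HCT116 and KRT20 at 10.92 and 6.78 in DLD1. For every gene shown the points of both genotypes do not overlap in its line, which was a condition for being chosen.

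Genes of the amino acid stress response, driven by ATF4, rose in DLD1 mutant-only cells. Of 29 members 16 rose and none fell (20 and 0 adjusted over the list alone), with a median log2 change of 0.32 and a camera adjusted p of 1.12e-10 (adjusted p = 0.111 with an estimated correlation). DDIT4 rose 2.40-fold, from 8.10 ± 0.55 to 9.36 ± 0.21 (SD, n = 3, adjusted p = 0.00119), the leucine sensor SESN2 by 0.72, PHGDH, the first enzyme of serine synthesis, by 0.71 and its partner enzyme PSPH by 0.56. The lipoprotein receptor VLDLR rose by 0.85 (SE 0.0815, adjusted p = 2.26e-05). Heat shock and unfolded protein genes rose as well, 7 of 19 with none falling (10 and 0 adjusted over the list alone, camera adjusted p = 6.33e-07, adjusted p = 0.101 with an estimated correlation). Among those that passed were the transcription factor XBP1 by 0.36 (adjusted p = 0.00936) and the chaperone cofactor SDF2L1 by 0.36, a call lost without the arrays numbered 3 (0.0736). Glycolysis and HIF targets gave 6 higher and 3 lower of 29 (8 and 3 alone, camera adjusted p = 0.0181, adjusted p = 0.463 with an estimated correlation). Hexokinase HK2 rose by 0.66 and the oxygen-sensing hydroxylase EGLN3 by 0.67, whereas ENO2 fell by 0.36. The glycolysis call was lost without DLD1 wild-type-only replicate 3 (0.136), mutant-only replicate 1 (0.0886) or mutant-only replicate 2 (0.0687), with dim genes left out (0.121) and after cyclic loess (0.149).

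TGF-beta and YAP targets fell in DLD1. Of 24 members 9 fell and TGFB2 rose (13 and 1 adjusted over the list alone), with a median log2 change of -0.19 and a camera adjusted p of 3.91e-08 (adjusted p = 0.101 with an estimated correlation). ANKRD1 fell from 9.93 ± 0.20 to 8.33 ± 0.10 (SD, n = 3), PMEPA1, a TGF-beta target, fell by 0.75 (adjusted p = 3.51e-05), TGFBI fell by 0.62 and the BMP target ID1 fell by 0.60. Receptor tyrosine kinases and adaptors fell, 6 of 25 with none rising (9 and 0 adjusted over the list alone, camera adjusted p = 0.000384, adjusted p = 0.243 with an estimated correlation). IGF1R, the receptor for insulin-like growth factor, fell from 10.01 ± 0.08 to 8.72 ± 0.06 (SD, n = 3), which was 2.44-fold lower (adjusted p = 1.67e-08), and ERBB3 fell by 0.29, a call lost without the arrays numbered 3 (0.0577). FOXO-activated genes, which include IGF1R and ERBB3, gave 6 lower and 1 higher of 24 (7 and 1 alone, camera adjusted p = 0.000946, adjusted p = 0.266 with an estimated correlation), with SESN3 falling by 0.86 and the mTOR complex 2 subunit RICTOR by 0.32. ERK pathway output gave 6 lower and 2 higher of 26 (8 and 2 alone, camera adjusted p = 0.0281, adjusted p = 0.642 with an estimated correlation): the phosphatase DUSP6 fell by 0.58 and JUN fell by 0.48, while ETV1 rose by 0.38. The ERK call was lost without DLD1 wild-type-only replicate 2 (0.0821), wild-type-only replicate 3 (0.0813) or mutant-only replicate 1 (0.103) and by fry (0.178).

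Matrix remodelling and invasion genes gave 8 lower and 1 higher of 34 in DLD1 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00181, adjusted p = 0.244 with an estimated correlation). The integrin subunit ITGB6 fell from 8.47 ± 0.12 to 7.32 ± 0.12 (SD, n = 3, adjusted p = 3.42e-06), the hyaluronan receptor CD44 fell by 0.89 and ITGB4 fell by 0.46. Of 35 interferon-stimulated genes 4 fell and none rose (4 and 0 adjusted over the list alone, camera adjusted p = 0.0185, adjusted p = 0.111 with an estimated correlation, adjusted p = 0.101 with low-signal members left out). MX2 fell by 0.70, the immunoproteasome subunit PSMB9 by 0.64, IFIT3 by 0.57 and OAS1 by 0.45, of which OAS1 lost its call without the arrays numbered 3 (0.0649). HLA and antigen presentation genes gave 2 lower of 13, PSMB9 and TAPBP (5 adjusted over the list alone, camera adjusted p = 0.0185, adjusted p = 0.111 with an estimated correlation, adjusted p = 0.0574 with low-signal members left out). The TAPBP call was lost without DLD1 wild-type-only replicate 3 (0.127), mutant-only replicate 1 (0.125), mutant-only replicate 2 (0.11) or mutant-only replicate 3 (0.0503).

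Epithelial junction and keratin genes did not pass in DLD1 (2 higher and 3 lower of 27; 2 and 3 adjusted over the list alone, camera adjusted p = 0.0922). KRT20 belongs to them, the desmosomal cadherin DSC2 was 2.20-fold lower (adjusted p = 9.21e-06) and the tight junction protein TJP3 rose by 0.67. The same list passed by fry (0.000742), with dim genes left out (0.0222), after quantile normalization (0.0179), after cyclic loess (0.00559) and without DLD1 mutant-only replicate 2 (0.0437). It did not pass by camera with an estimated correlation (adjusted p = 0.44) or with the replicate number as a block (adjusted p = 0.0748). Intestinal differentiation genes gave 5 higher and 4 lower of 34 (7 and 5 alone, 0.807), since KRT20 and MUC1 fell while MUC13, CA2 and CDH17 rose by 1.40, 0.86 and 0.60; the mean was below 0 and camera's direction was up. Mesenchymal genes gave 3 and 2 of 28 (3 and 3 alone, 0.726), with the matrix protein TNC rising 2.56-fold, and here the mean was above 0 and camera's direction was down. PI3K, AKT and mTOR components gave 3 and 1 of 26 (3 and 1 alone, 0.229). NF-kB targets and chemokines gave 3 and 0 of 23 (3 and 0 alone, 0.464) with the chemokine CXCL5 rising 2.12-fold, and sterol and fatty acid synthesis 2 and 0 of 24 (3 and 0 alone, 0.464), FADS2 and ELOVL6. WNT targets and stem cell genes gave 1 and 1 of 22 (1 and 1 alone, 0.458), p53 targets 1 and 1 of 22 (1 and 2 alone, 0.464) and autophagy and lysosome genes 0 and 1 of 24 (0 and 0 alone, 0.808, mean 0.0133 and median -0.00621). Of 38 cell cycle genes 1 rose (0 and 0 alone, 0.072). The list passed with the replicate number as a block (0.0193) and without DLD1 wild-type-only replicate 1 (0.0441), wild-type-only replicate 2 (0.0293) or mutant-only replicate 3 (0.0262). Camera with an estimated correlation (adjusted p = 0.808) and fry (adjusted p = 0.453) did not call it.

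Markers of cell types other than epithelium were followed as well. In DLD1 none of 11 fibroblast, 11 leukocyte and red cell and 9 endothelial markers changed, nor any of 15 cancer-testis antigens, in limma's test adjusted over all genes or over each list alone. In HCT116 the same held except for the leukocyte marker LYZ, which fell by 0.22 (adjusted p = 0.0473) and lost its call without HCT116 wild-type-only replicate 1 (0.0612), 2 (0.139) or 3 (0.113), mutant-only replicate 1 (0.187) or mutant-only replicate 3 (0.097). The camera adjusted p of the fibroblast, leukocyte, endothelial and cancer-testis lists was 0.137, 0.721, 0.384 and 0.392 in HCT116 and 0.464, 0.768, 0.277 and 0.277 in DLD1. In DLD1 the leukocyte list had a mean of -0.0136 and a median of 0.00511.

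The third comparison asked which changes both lines shared. DPP4 rose in both, 4.27-fold in HCT116 and 2.15-fold in DLD1 (adjusted p = 4.25e-05), as did DDIT4 (2.08-fold and 2.40-fold), TENM3 (3.33-fold and 1.68-fold) and SAMD5 (1.63-fold and 1.84-fold). The fatty acid-sensing nuclear receptor PPARG rose 1.57-fold from 9.59 ± 0.04 (SD, n = 3, adjusted p = 1.52e-05) in HCT116 and 1.55-fold from 9.41 ± 0.05 (SD, n = 3, adjusted p = 1.31e-05). SPTSSB was lower in both (4.51-fold and 1.45-fold), with the lipid transfer protein OSBPL8 (1.45-fold and 1.54-fold), the glutamate transporter SLC1A3 (1.44-fold and 1.60-fold), MAOB (1.40-fold and 3.37-fold) and the Notch coactivator MAML3 (1.68-fold and 1.40-fold). Among list genes PIK3R3 rose in both lines by 1.32 and 0.39, and DUSP5 and SPRY4 fell in both, each by 0.42 in HCT116 and by 0.28 in DLD1, where the DUSP5 call was lost without DLD1 mutant-only replicate 1 (0.0527). Without the arrays numbered 3 of all groups the DLD1 calls of DUSP5 (0.0943), SPRY4 (0.0543) and MAML3 (0.0969) were lost. SLC7A11 rose by 0.61 in both but lost its DLD1 call without wild-type-only replicate 1 (0.0902), wild-type-only replicate 3 (0.0685) or mutant-only replicate 1 (0.0977), 2 (0.0859) or 3 (0.0618). KLF7 fell in both, by 0.52 and 0.47, and lost its DLD1 call without wild-type-only replicate 3 (0.0603) or mutant-only replicate 1 (0.0652) or 2 (0.0632).

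A total of 131 genes changed in the same direction in both lines. Of these, 92 were higher against 41.8 for independent lists (odds ratio 2.50, Fisher's exact test, two-sided, p = 7.49e-13) and 39 lower against 12.2 (odds ratio 3.60, p = 1.84e-10). Opposite directions also exceeded that number: 45 genes were higher in HCT116 and lower in DLD1 against 22.9 (Fisher's exact test, p = 1.77e-05), and 49 were lower in HCT116 and higher in DLD1 against 22.3 (Fisher's exact test, p = 2.15e-07). These tests are over genes, which are not independent replicates. Across all 18377 genes the changes of the lines correlated with r = 0.0822 and a Spearman rho of 0.147, and the comparisons share no arrays. From the arrays of 1 replicate number alone r was 0.153 for replicate 1, 0.031 for replicate 2 and -0.0013 for replicate 3, and without HCT116 wild-type-only replicate 1 it was 0.046. The blocked fit gave 273 genes in the same direction. The number was 74 without HCT116 mutant-only replicate 1, 81 without DLD1 wild-type-only replicate 1, 81 without DLD1 mutant-only replicate 1, 81 with each line's own arrays in the fit, 72 without the arrays numbered 3 and 269 with array weights.

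The mean of both lines passed for 1774 genes, 1145 higher and 629 lower, for 2813 with the replicate number as a block and for 3524 with array weights (2192 higher, 1332 lower). At least 2-fold mean changes were found for 17 genes. Higher calls made up 64.5%, and 82.1% of 2465 after median centring of each array (2023 higher, 442 lower). On this mean 17 of 29 amino acid stress response genes rose and none fell (20 and 0 adjusted over the list alone, camera adjusted p = 8.02e-13, adjusted p = 0.122 with an estimated correlation). FOXO-activated genes were lower, as 9 of 24 fell and 1 rose (10 and 3 alone, camera adjusted p = 0.007, adjusted p = 0.36 with an estimated correlation), and so was ERK output, of which 7 of 26 fell and 1 rose (8 and 2 alone, camera adjusted p = 0.00187, adjusted p = 0.36 with an estimated correlation). The FOXO list did not pass in HCT116 (list mean -0.0202, camera adjusted p = 0.384). Its list mean was -0.164 in DLD1, so the fall lay mainly there. Camera called 14 of the 24 lists on the mean of lines and none with an estimated correlation.

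The fourth comparison tested the difference between the changes of the lines, HCT116 minus DLD1. KRT20 differed most: its log2 change was 0.23 in HCT116 (adjusted p = 0.0844) and -4.14 in DLD1, a difference of 4.37 (SE 0.0999, adjusted p = 2.2e-11). VGLL1 differed by 2.83, APOBEC3G by 1.88 and the zinc finger gene ZNF675 by 1.98 (0.64 in HCT116 and -1.33 in DLD1). QPRT differed by -2.86, HLTF by -2.83, SH3BGRL by -2.43, GPR15 by -2.39 and GALNT5 by -2.36 (-1.96 in HCT116 and 0.40 in DLD1). Some levels were low in the other line, where a fall may not show, though signal over background was not assessed. Clusters with no symbol averaged 6.44, and the lower quartiles of the arrays were 6.021 to 6.081. GPR15 lay at 5.54 to 5.96 in DLD1, and VGLL1 at 6.54 to 6.87 and APOBEC3G at 6.47 to 6.90 in HCT116. This was not so for HLTF (10.607 to 10.785 in HCT116) and SH3BGRL (11.985 to 12.211). ZNF675 and GALNT5 were called in both lines with opposite signs. Ranked by the smaller of both changes, genes called with opposite signs were led by the adhesion receptor ADGRF1 (0.93 and -1.01), the MAP kinase phosphatase PTPRR (-0.72 and 0.72), the GTPase RHOU (0.83 and -0.68) and the clock gene BMAL1 (-0.95 and 0.65). The DLD1 call of BMAL1 was lost without DLD1 wild-type-only replicate 3 (0.118), mutant-only replicate 1 (0.116), mutant-only replicate 2 (0.054) or mutant-only replicate 3 (0.0685).

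In all, 1307 genes differed between the lines, 677 with the more positive change in HCT116 and 630 in DLD1, with 105 at a difference of at least 2-fold. Which line had more of these depended on the processing: the split was 566 and 720 after median centring, 520 and 594 without HCT116 wild-type-only replicate 1, 1060 and 1129 of 2189 with array weights, and 1036 and 1041 of 2077 in the blocked fit. Of the 24 lists, p53 targets and TGF-beta and YAP targets differed between lines with an estimated correlation (adjusted p = 0.0131 and adjusted p = 0.0484). The latter lies close to the threshold. List tests of the difference between lines were not repeated with arrays left out or under other normalizations. Of 22 p53 targets 9 had the more positive change in HCT116 and none in DLD1 (10 and 1 adjusted over the list alone, camera adjusted p = 1.13e-07), CDKN1A by 0.76 (SE 0.126) and MDM2 by 0.49. Of 24 TGF-beta and YAP targets 10 had the more positive change in HCT116 and none in DLD1 (14 and 1 adjusted over the list alone, camera adjusted p = 5.52e-10), ANKRD1 by 1.65 and PMEPA1 by 0.89. ANKRD1 lay at 6.04 to 6.32 in HCT116, where a fall may not show. Heat shock and unfolded protein genes went the other way, 5 of 19 (7 adjusted over the list alone, camera adjusted p = 2.42e-06, adjusted p = 0.0856 with an estimated correlation), with the mitochondrial chaperonin HSPD1 at -0.54.

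**Figure D2:**
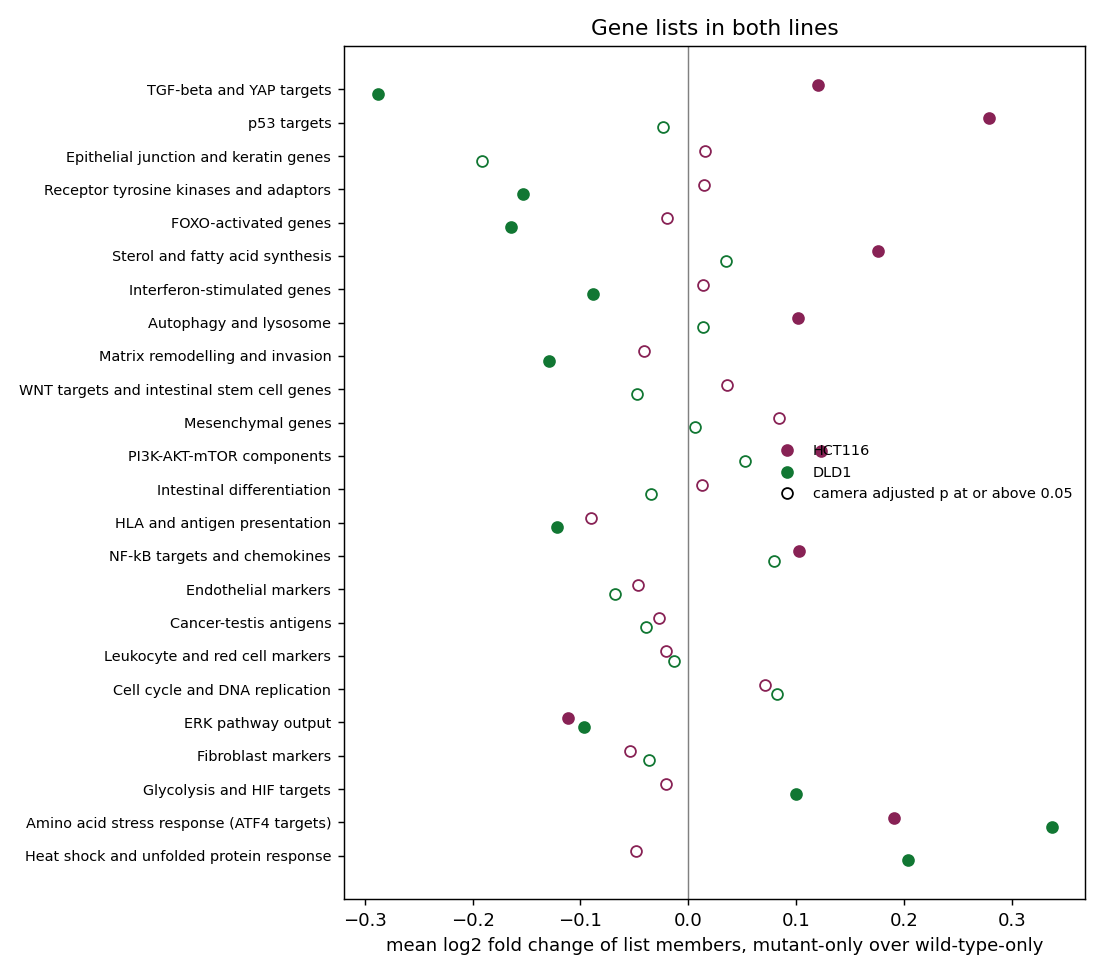
Mean log2 fold change of the measured members (x axis) for each of the 24 gene lists (y axis), 1 point per list and line, HCT116 in purple and DLD1 in green; open points did not pass camera's test, at an adjusted p of 0.05 or more, and no error is drawn. The p53 targets lie at 0.28 in HCT116 and -0.02 in DLD1, and the TGF-beta and YAP targets at 0.12 and -0.29.

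**Figure D3:**
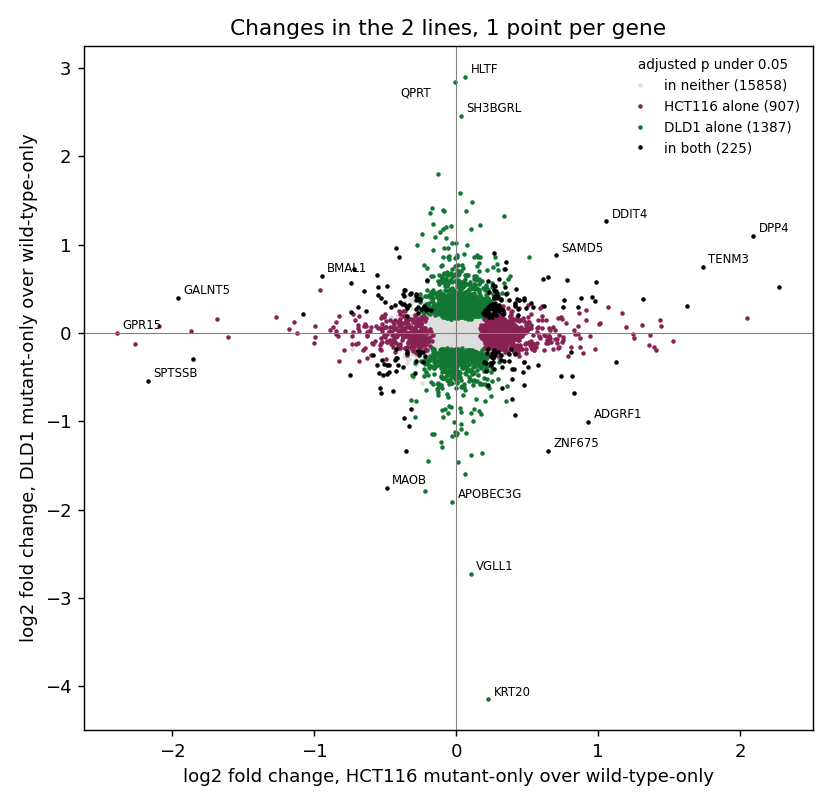
Log2 fold change in HCT116 (x axis) and DLD1 (y axis), mutant-only over wild-type-only, 1 point per gene for 18377 genes, coloured by the lines in which the adjusted p was under 0.05. DPP4 lies at 2.09 and 1.10, KRT20 at 0.23 and -4.14, and the changes of the lines correlated with r = 0.0822 across genes.

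The authors' deposited tables list clusters for 1 line each, and each table was assigned to its line because its group values equal the group means of that line's arrays. For HCT116 the authors' deposited table holds 35 transcript clusters, 18 higher and 17 lower in mutant-only cells, led among clusters with a symbol by EHF (4.85-fold), DPP4 (4.27-fold) and BDNF (4.13-fold) and by GPR15 (5.23-fold lower), SCG2 (4.81-fold lower) and SPTSSB (4.51-fold lower). For DLD1 the authors' deposited table holds 44, 23 higher and 21 lower, led in the same way by HLTF (7.45-fold), QPRT (7.18-fold) and SH3BGRL (5.50-fold) and by KRT20 (17.7-fold lower), VGLL1 (6.60-fold lower) and MAOB (3.37-fold lower). All 35 and all 44 passed with the same sign in a limma fit over every transcript cluster, and the fold changes correlated with r = 1, as both come from the same values. An unadjusted p under 0.05 with at least a 2-fold change was met by 44 clusters in HCT116 and 62 in DLD1, so 9 and 18 that met it are not in the authors' deposited tables. PIK3R3, ZNF711 and LRIG1 in HCT116 and CELF2, APOBEC3G and HOXD10 in DLD1 are among these. The highest array of each listed cluster was at least 8.82 in HCT116 and 8.84 in DLD1, and that of the others at most 8.78 in both. Signal thus parted listed from unlisted clusters fully, so the unlisted ones need not have met every rule of the authors' selection.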

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

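The tests of p53 activity by line and the cyclic loess were chosen only after the results were seen; the other tests in this part were chosen earlier. The change from wild-type-only to mutant-only differed between the lines for 1307 genes. KRT20 differed by 4.37 on the log2 scale (HCT116 minus DLD1), VGLL1 by 2.83, ZNF675 by 1.98, ADGRF1 by 1.94 and APOBEC3G by 1.88. QPRT differed by -2.86, HLTF by -2.83, SH3BGRL by -2.43, GPR15 by -2.39 and GALNT5 by -2.36. Low levels in the other line may limit the reading of GPR15, VGLL1 and APOBEC3G, as given above. Opposite changes, each past the threshold in both lines, gave differences of -1.44 for PTPRR, 1.52 for RHOU and -1.59 for BMAL1.

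Mean changes of 13 gene lists differed between lines in camera's test. The difference was 0.408 for TGF-beta and YAP targets and 0.302 for p53 targets, the 2 that held with an estimated correlation. It was -0.253 for heat shock and unfolded protein genes, 0.168 for receptor tyrosine kinases and adaptors, -0.146 for the amino acid stress response, 0.144 for FOXO-activated genes, 0.141 for sterol and fatty acid synthesis, -0.121 for glycolysis and HIF targets and 0.102 for interferon-stimulated genes. It was 0.206 for epithelial junction and keratin genes, 0.0888 for autophagy and lysosome genes, 0.0879 for matrix remodelling and 0.078 for mesenchymal genes, and these 4 did not pass with the replicate number as a block (adjusted p = 0.0686, 0.0535, 0.0921 and 0.0615).

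Transcript clusters with no symbol here, which the comparisons of genes did not use, also held differences: 95 of 7807 passed in HCT116 (35 higher, 60 lower; 1.22% against 5.06% of clusters with a symbol) and 89 in DLD1 (48 higher, 41 lower; 1.14% against 7.41%). Their mean level was 6.44 on the log2 scale, against 8.16 for those with a symbol.

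The p53 targets rose in HCT116 and not in DLD1, and the difference was tested. A shift that depends on signal level is argued against as the whole cause, since after cyclic loess the list's median was 0.208 (0.221 before) and its adjusted p 0.00207 with an estimated correlation. A single array is argued against as the cause of the rise by the list mean. It was 0.279 with all arrays and 0.257 to 0.298 with each HCT116 array left out in turn. The camera adjusted p was then 1.06e-10 to 4.62e-09 at the preset correlation, where calls are weak by themselves. The test with an estimated correlation was not repeated with arrays left out. Whether p53 activity differed between both derived HCT116 lines is left open: HCT116 has an intact p53 gene and DLD1 a mutated one, but the difference between lines (adjusted p = 0.0131 with an estimated correlation; DLD1 median -0.0315, adjusted p = 0.71 with an estimated correlation) restates the result that raised the question. Whether the allele kept or another difference between the derived lines lies behind it was not tested.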

How the results depend on the processing

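Cyclic loess, the block shared by both lines, the arrays numbered 3 left out together and the lists without low-signal members were chosen only after the results were seen. No named gene or list turned its direction in an alternative where it passed in the main fit or in that alternative. Turns where neither passed were not counted. Among these, fry gave the opposite direction to camera for intestinal differentiation genes in both lines and for WNT targets in HCT116. Which line had more of the genes that differed between lines also reversed, as given above. The total counts were within 1.5 times of those reported with the mean of clusters, dim genes left out, quantile normalization, median centring, trend and robust settings, cyclic loess and every cluster. With a replicate block within each line the counts were 1808 in HCT116, 2482 in DLD1, 2813 for the mean and 2077 for the difference. It gave 273 genes changed in the same direction in both lines. With 1 block per number over both lines the counts were 1855, 2621, 2954, 2120 and 281, in the same order. The block, beyond this, changed only the list calls given above. The pairing behind it was less clear in DLD1. With each line's own arrays HCT116 had 665 and 81 genes were shared; the smaller number of arrays gives fewer degrees of freedom. Array weights gave 4705 in DLD1, 3524 for the mean, 2189 for the difference and 269 shared. Without the arrays numbered 3, DLD1 had 995 and 72 were shared. At least 2-fold changes numbered 38, 54, 17 and 105; with an unadjusted p, by limma or by a plain test, they were 38 and 54. Leaving out 1 array gave 681 to 932 in HCT116, 939 to 1379 in DLD1 and 74 to 114 shared. Camera with an estimated correlation called 1 list in HCT116 and 0 in DLD1. Other alternatives called 6 to 10 lists in HCT116 and 8 to 11 in DLD1, and fry's mixed test, which ignores direction, 19 and 18. The correlation between lines was 0.046 to 0.104. Of 2775 alternative values for 162 named results 2587 kept their side of the threshold and 188 did not, 128 of them with 1 array left out; 123 results never changed. Of 663 for 37 further values of genes chosen after they were seen, of which some are named above, 620 kept it and 43 did not, 25 of them with 1 array left out. SLC7A11, LYZ, BAX, STC2, TAPBP and BMAL1 lost calls in other settings too. The cause was not tested where none is given. The alternatives set for the transcript of the targeted gene were not run. Signal over background was not assessed, which limits what can be said of low-signal genes.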

Other observations

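The tests of cross-hybridisation, the cyclic loess and the 32 splits that part every pair were chosen only after the results were seen; the other splits of the arrays, the test within signal bins and the test of neighbouring genes were chosen before their results were seen. Zinc finger genes, taken by symbols that start with ZNF, ZFP or ZSCAN, were a group outside the lists, chosen after several of its members were seen among the largest changes. In HCT116 58 of 532 changed (10.9%), against 1074 of 17845 other genes (6.02%, odds ratio 1.91), 50 of them higher and 8 lower. The largest changes were those of ZNF711 (1.63, adjusted p = 4.64e-09), ZNF566 (1.37) and ZNF136 (1.36), which rose, and ZNF426, which fell by 1.61, and ZNF280A, which fell by 1.18. In DLD1 34 changed, an odds ratio of 0.704, and whether the odds ratios differ between lines was not tested.

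Low signal of these genes is argued against as the whole cause: within 10 bins of mean signal the HCT116 odds ratio was 2.18 (95% interval 1.64 to 2.9, taking genes as independent, which neighbours are not). Many such genes lie next to one another, and neighbours changing together may account for part of the count: 29.3% of the 58 (17; 95% interval 18.1% to 42.7%) had no called gene of the same sign among the 5 nearest genes on each side, against 60.2% of the other called genes. Of the 41 with such a neighbour, 28 had another zinc finger gene as one. Cross-hybridisation among related probes cannot be told apart from a change of many genes, because either could move most of them one way. The 86.2% with the more frequent sign also has a 95% interval of 74.6% to 93.9%, which reaches to both sides of the bound set for it. No biological explanation was tested.

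More genes were higher than lower in both lines. After cyclic loess, which removes a shift that depends on signal level, 63.6% of calls were higher in HCT116 and 61.5% in DLD1. The share depends on the scaling: it was 60.9% and 56.6% after quantile normalization and 72.8% and 80.1% after median centring. Upper quartiles were higher in every mutant-only array, at 9.132 to 9.139 against 9.079 to 9.119 in HCT116. In DLD1 they were 9.193 to 9.2 against 9.143 to 9.165. Such a shift is argued against as the whole cause by cyclic loess only, and quantile normalization leaves it open in DLD1. A change in the total amount of RNA per cell was not tested.

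Regrouping the arrays tested the counts against chance. For a single line the 3 against 3 arrays make 10 splits, too few for a share under 0.05: the real split, 1 of 10, gave 1132 genes in HCT116 and 1612 in DLD1 with 0 in the highest other split, and 8 and 10 called lists with 7 in the highest other split of each line. The 3 other splits that part every same-numbered pair as the real one does gave at most 0 genes, and at most 7 lists in HCT116 and 6 in DLD1. List calls at the preset correlation thus arose in splits without any called gene, and do not by themselves show a difference of genotype. Of 100 splits drawn within both lines, 1 gave as many genes on the mean of lines (1774, highest other 1307). Of all 32 splits of both lines that part every same-numbered pair it was again 1. A chance arrangement of the arrays is argued against for this count, but other differences between the derived lines are not. Nor does the count speak for a shared change, since the 1307 came from the real split with the DLD1 labels exchanged. For genes shared in direction, 1 of 100 gave as many (131; highest other 94), but the test says nothing about sharing, since every split other than the real one and its mirror gave 0. For the difference between lines (1307) 2 of 100 splits did, and 2 of the 32, which is a share above 0.05. The second split, with 1774, is the real one with the DLD1 labels exchanged, which turns the difference into the mean, and the highest of the rest among the 32 gave 320. Chance cannot be excluded for the correlation between lines, as 24 of 100 splits gave an r of 0.0822 or more (highest other 0.376), and 8 of the 32.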
